A study of Anolis carolinensis with 142 samples.

How the data were processed

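RNA of 142 tissue samples from 24 green anoles was sequenced, 1 library per tissue and animal, and the deposited values are raw read counts per Ensembl gene ID, 26479 IDs in all. Per the submitters' processing notes, Trimmomatic, FastQC, STAR 2.7.11a, featureCounts and Subread were used, with no role or order given. The genome build, the annotation release, and whether strand or reads that map to several places were taken into account are not given in the sources used here. Without the strand setting, reads of overlapping and antisense genes cannot be told apart, and closely related genes may share reads. The deposited table also gives each gene's coordinates and its length in bases, which equalled its merged exons in 100% of genes. Coordinates are printed as that table gives them.

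The gene IDs could not be paired with names. Of the IDs, 0 matched the 27148 rows of the RefSeq gene table used (assembly rAnoCar3.1), and the table of counts pairs no ID with a name. The 51 gene lists fixed before the data were examined, the test of clock genes between tissues and the planned rule for named genes were therefore not run. In their place at most 1 ID per direction was printed for each of the comparisons Midnight against Midday and ALAN against Midnight, by a rule set after the ID problem was seen. It took called genes with a mean of at least 1 CPM and at least 0.75 of the libraries of a group beyond the median of the other, in tissues where the groups differed by at most 0.15 in the share of libraries in each counting class (described with the results). Among these, the ID called in the most tissues was taken for Midnight against Midday, and the ID of largest absolute log2 change for ALAN against Midnight. Lists of tissue-enriched genes (mean level at least 5 CPM and at least 8-fold above that of every other tissue, both kinds of skin taken as a single tissue; 182 for brain, 206 for eye, 342 for liver, 385 for ovary, 247 for skin and 984 for testes), the mitochondrial genes, and the day-night genes of brain, eye and liver as sets for the other tissues were also added after the data were examined. The tissue-enriched lists were made from these same libraries.

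Genes were tested in each tissue separately with edgeR 4.0.16 in R 4.3.3: TMM normalization, filterByExpr on treatment by sex, robust quasi-likelihood fits of the 3 treatments with sex as a covariate, and Benjamini-Hochberg adjustment over the genes tested in the tissue, with calls at an adjusted p under 0.05. The effect of light by sex used a mean for each treatment and sex. Lists with at least 5 measured members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 and with an estimated one. The day-night score used genes called between Midday and Midnight replicates 1 and 2, or the 100 of smallest p where fewer than 20 were called. It was compared by a two-sided exact permutation test, adjusted over the 7 tissues. Recurrence across tissues was set against 1000 shuffles of gene labels. Whether a change differed between tissues was tested in a single edgeR fit of all libraries.

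On simulated counts with 200 changed genes for ALAN against Midnight, edgeR recovered 55.2%, 71.6% and 86.4% of genes changed by log2 values of 0.5, 1 and 2 in brain (17192 genes), with 8 false calls, and 4.48%, 43.3% and 66.7% in testes (17213 genes), with 5. Counting intervals cover counting error only. The alternatives fixed before the data were examined were size factors by RLE, no filter on low counts, DESeq2 1.42.0, the replicate number as a block, no sex term, a fit of the 2 groups alone, each library left out, and for the score an exchange of Midnight replicates 1 and 2 with 3 and 4 and the 100 genes of smallest p. The counting class as a term, fits within 1 class, fits without the 11 libraries that stood apart (median correlation over 5 median absolute deviations below that of the tissue), an offset per gene for the counting class estimated in other tissues, and score genes from other tissues were added later. A first version of that offset, which shrank the effects, moved no call and was replaced by 1 that uses effects over 2 standard errors. Each animal had 1 treatment, so replicate numbers do not pair treatments. Tables were handled with Python 3.11.15 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.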

Results

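RNA sequencing counts were examined for 24 adult green anoles (*Anolis carolinensis*), small diurnal lizards caught in the wild. Each animal had been given 1 of 3 treatments. Midday animals were dissected by day, Midnight animals at night without added light, and ALAN animals at night under artificial light. Each treatment held 4 males and 4 females. The 142 libraries covered 7 tissues: brain (taken with the pineal gland, which makes the night hormone melatonin), eye, dorsal skin, ventral skin, liver, testes and ovary. There were 24 libraries each of brain, eye and liver, 23 of each kind of skin, and 12 each of testes and ovary. Total counts per library ran from 10257388 to 30952365, with a median of 21039521. The labels gave the same batch for every library.

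The libraries fell into 2 classes by a property of the counts themselves. In 100 libraries, 58.8% to 72.6% of the counts from 1 to 20 were even numbers, and totals ran from 17129400 to 30952365. In the other 42, the share was 40.5% to 44.4%, and totals ran from 10257388 to 16304907. The low-share class held 0 of the 24 brain libraries, but all 8 ALAN libraries of liver and all 4 of testes, against 0 of the Midday and Midnight libraries of those tissues. It also held 7 of 8 Midday, 7 of 8 Midnight and 1 of 8 ALAN eye libraries, 6 of 8 Midday libraries of dorsal skin, 5 of 8 ALAN and 1 of 7 Midday libraries of ventral skin, and 3 of 4 ALAN libraries of ovary. In liver and testes the class and the light treatment cannot be told apart.

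**Figure D1:**
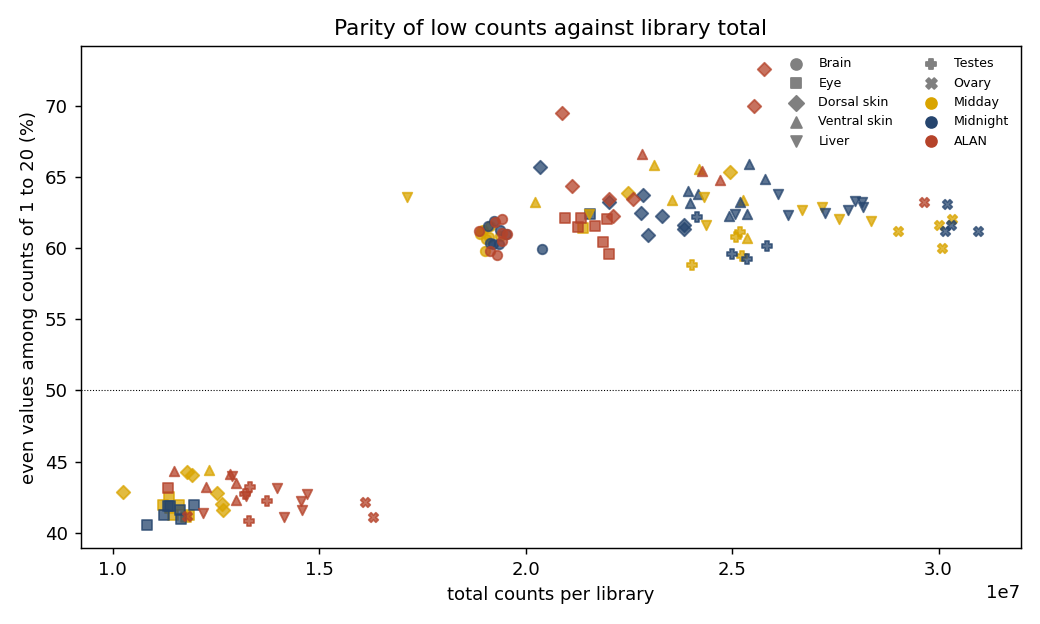
Share of even values among counts of 1 to 20 (vertical axis, %) against the total count of each library (horizontal axis, counts), with tissues as marker shapes and treatments as colours. The 42 libraries under the dotted line at 50% have totals of at most 16304907, and the 100 above it have at least 17129400.

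Midnight against Midday measured the difference between night and day without added light. The largest numbers of genes differed in eye (720, with 316 higher and 404 lower at Midnight), liver (309, with 102 higher and 207 lower) and brain (207, with 62 higher and 145 lower). In dorsal skin 8 genes were higher and 27 lower, and in ventral skin 5 were higher and 5 lower, by edgeR at an adjusted p under 0.05. In dorsal skin, where 6 of 8 Midday and 0 of 8 Midnight libraries were of the low-share class, 6 genes were called with the class as a term, 3 of them among the 35. The brain library of Midnight female 4 held 1.86% of its counts in genes enriched in ovary, against at most 0.159% in the other Midnight brain libraries, and without it 257 genes were called in brain. With single libraries left out the counts ran from 347 to 1792 in eye, 146 to 383 in liver, 154 to 257 in brain, 18 to 54 in dorsal skin and 7 to 62 in ventral skin. The median absolute log2 change of the genes called was 0.51 in brain, 0.56 in eye and 0.94 in liver. Across tissues, 24 genes were higher at Midnight in at least 2 tissues and 78 were lower, where shuffled gene labels gave means of 3.16 and 11.7. The shuffles treat tissues as independent, although the same animals supplied them.

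ENSACAG00000002847, a gene of 8 exons on chromosome 6 (69322100 to 69337242, minus strand), was higher at Midnight in brain, eye, both kinds of skin and liver. In the eye it rose from 52.2 ± 13.1 CPM (SD, n = 8; CPM are counts scaled by the library total) at Midday to 474 ± 41.9 at Midnight (n = 8), a log2 change of 3.20 ± 0.12 (SE, adjusted p = 8.42e-15, edgeR), and all 8 Midnight libraries exceeded every Midday library. Its log2 change was 1.82 in brain, 2.42 in dorsal skin, 2.56 in ventral skin and 1.66 in liver. In the 2 gonads the log2 values of 0.91 (testes) and 0.32 (ovary) did not pass the test, and the change differed between tissues (adjusted p = 3.40e-07, edgeR). This fit over all libraries, like those for the other genes, took no account of the same animals supplying several tissues. ENSACAG00000002744, a gene of 22 exons on chromosome 3 (28004348 to 28050917, plus strand), was lower at Midnight in the same 5 tissues. In brain it fell from 466 ± 38.9 CPM at Midday to 198 ± 47.9 at Midnight (n = 8 each), a log2 change of -1.24 ± 0.11 (SE, adjusted p = 8.80e-08, edgeR). Its log2 change was -0.89 in eye, -1.74 in dorsal skin, -1.78 in ventral skin and -1.63 in liver, against -0.11 in testes and -0.08 in ovary, where it did not pass the test (difference between tissues, adjusted p = 3.86e-04, edgeR).

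In the gonads edgeR called 0 genes between Midnight and Midday. At an unadjusted p under 0.05 there were 815 in testes and 593 in ovary, and DESeq2 called 21 and 66. In the eye, 664 genes were called with the counting class as a term, 631 of them among the 720. A fit of the eye libraries of the low-share class, which leaves out the ALAN group, gave 120, a fit of the Midday and Midnight libraries alone 297, and 223 were called without the 3 eye libraries that stood apart from the others.

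**Figure D2:**
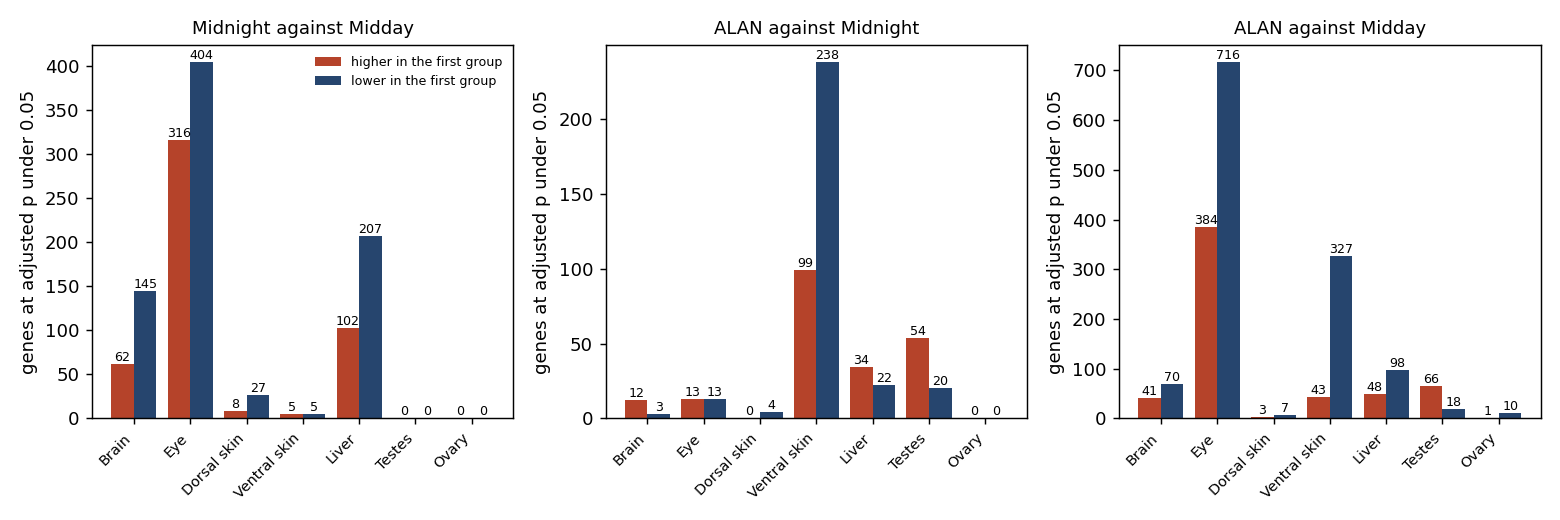
Number of genes past an adjusted p of 0.05 (edgeR, vertical axis) in each tissue (horizontal axis) for the 3 comparisons, split by direction in the group named first. In these fits the eye has the most genes against Midday (720 and 1100), and ventral skin the most between ALAN and Midnight (337). With the counting class as a term, ALAN against Midday gave 86 in eye and 128 in ventral skin.

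**Figure D3:**
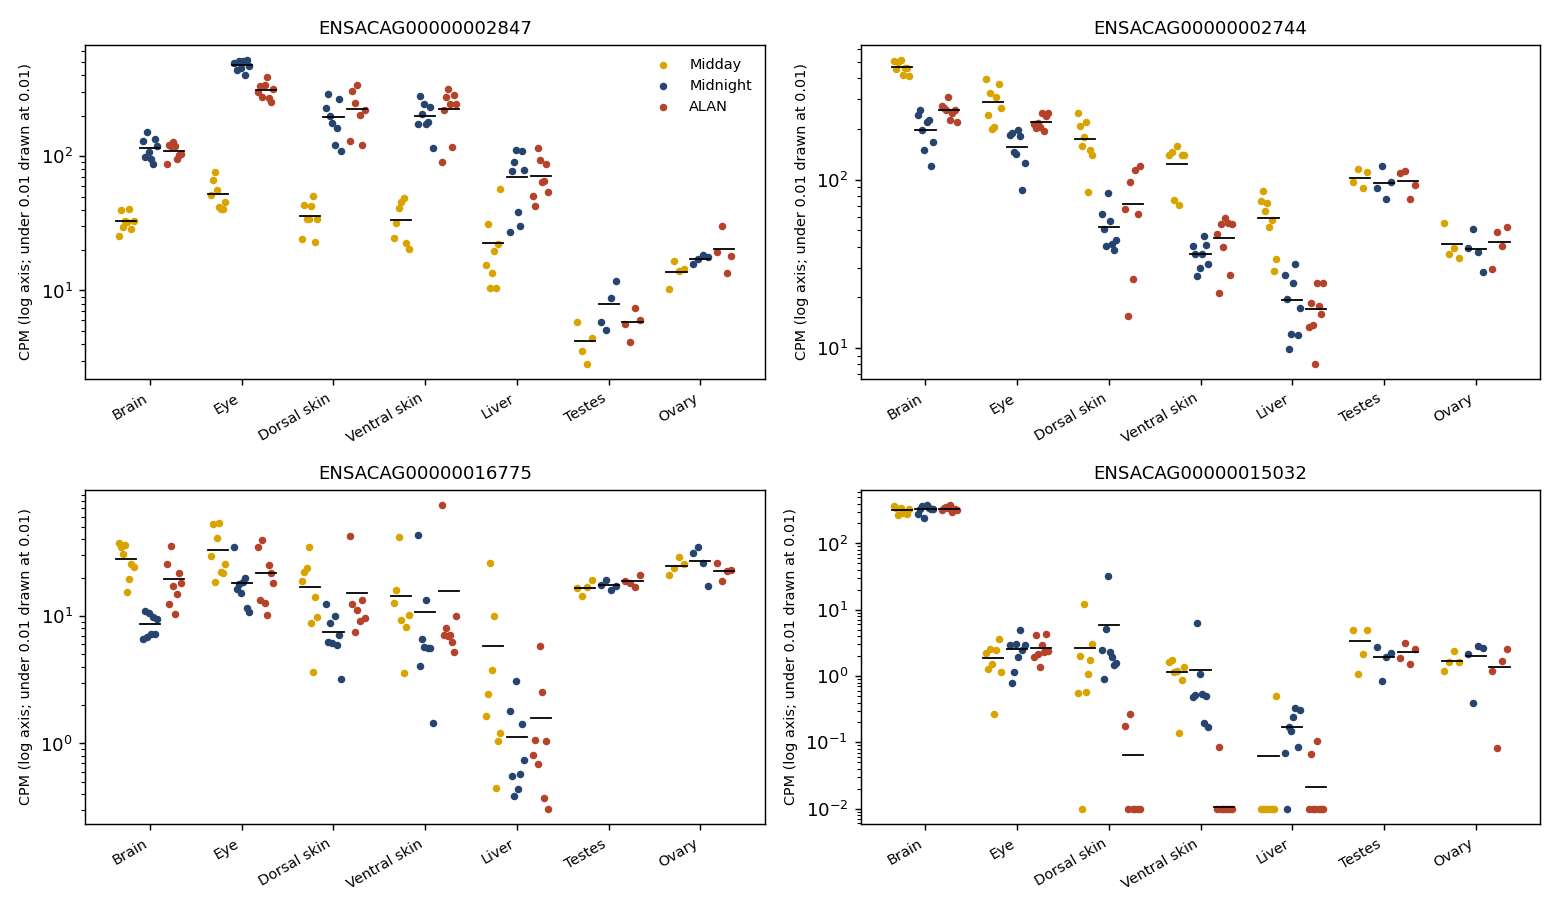
CPM of 4 genes in every library (vertical log axis, values under 0.01 drawn at 0.01) by tissue and treatment, with the group mean as a bar. ENSACAG00000002847 is higher and ENSACAG00000002744 lower at Midnight than at Midday in brain, eye, skin and liver, and ENSACAG00000015032 lies near 0 in the ALAN libraries of both kinds of skin.

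ALAN against Midnight compared a lit night with a dark night, sampled over the same hours. In brain 12 genes were higher and 3 lower under light, with a median absolute log2 change of 0.59. Single omissions moved this count of 15 to between 6 and 21. ENSACAG00000016775, on chromosome 2 (92812476 to 92823211, plus strand), was among those that rose in brain. It stood at 28.0 ± 8.07 CPM at Midday, 8.62 ± 1.80 at Midnight and 19.5 ± 8.03 under ALAN (SD, n = 8 each), so that its night level was higher with light by a log2 change of 1.15 ± 0.20 (SE, adjusted p = 0.0144, edgeR). All 8 ALAN libraries lay above the Midnight median. In a fit of the ALAN and Midnight brain libraries alone, its adjusted p was 0.0821, and the brain count was 8. The change of this ID was not found to differ between tissues (adjusted p = 0.698, edgeR), so it was not shown to be particular to brain. ALAN libraries above the Midnight median were 7 of 7 in dorsal skin, 7 of 8 in ventral skin and 6 of 8 in liver. They were 5 of 8 in eye, 3 of 4 in testes and 0 of 4 in ovary.

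In the eye 13 genes were higher and 13 lower under ALAN, and single omissions gave 18 to 64 genes in all. ENSACAG00000002847, the gene that rose at night, was lower in the lit eye, at 309 ± 43.9 CPM (n = 8), a log2 change of -0.62 ± 0.11 from Midnight (SE, adjusted p = 0.0108, edgeR), and its log2 value of -0.08 in brain did not pass the test. With the counting class as a term in the eye fit, 5 genes were called, and all 5 were among the 26. All 26 kept their direction, with a median absolute log2 change of 0.73 before and 0.66 after, and the median SE rose from 0.12 to 0.15. Whether ENSACAG00000002847 was among the 5 was not examined.

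Ventral skin had the most genes between ALAN and Midnight, with 99 higher and 238 lower and a median absolute log2 change of 3.09. Of the 238 lowered genes, 116 had their highest level in brain, 49 in liver and 44 in eye among the tissues other than skin. The shares over all genes tested in ventral skin were not computed, so these counts alone point to no tissue. The mean level of the 238 genes was taken as log2(CPM + 1), with CPM scaled by the library total alone. It was 0.64 ± 0.17 under ALAN (SD, n = 8) against 1.77 ± 0.47 at Midnight (n = 8) and 1.78 ± 0.41 at Midday (n = 7). A gap between ALAN and Midnight follows from how these genes were chosen. ENSACAG00000015032, on chromosome 3 (199188815 to 199427619, plus strand), was lower in both kinds of skin. In dorsal skin it held 10 counts over 7 ALAN libraries, 5 of them at 0, against 1183 over 8 Midnight libraries, a Midnight to ALAN ratio of pooled shares of 104 (95% counting interval 56.4 to 218; edgeR adjusted p = 0.0448). Midnight female 4 held 816 of these counts and also the most counts in brain-enriched genes (0.390%, next 0.0938%), and without it the ratio was 36.9 (19.9 to 77.7) and the log2 change -5.38 (edgeR adjusted p = 0.112). In ventral skin it held 1 count over 8 ALAN libraries against 248 over 8 Midnight libraries, a ratio of 168 (29.8 to 6650; edgeR adjusted p = 8.02e-04). Midnight female 3 held 158 of these and the highest brain-enriched share of its group (0.0854%, next 0.0664%), and without it the ratio was 69.7 (12.2 to 2790; edgeR adjusted p = 6.09e-04). In brain it stood at 334 ± 26.0 CPM under ALAN and 325 ± 44.8 at Midnight (n = 8 each). At Midnight it stood at 1.24 ± 2.10 CPM in ventral skin and 5.96 ± 10.6 in dorsal skin (n = 8 each). Brain RNA in the Midnight skin libraries could thus give its counts there, and this was not told apart from a change in skin. The change differed between tissues (adjusted p = 5.82e-08, edgeR), but so did that of 13.7% of 20795 genes, and this ID was chosen for its large change in skin. The ventral skin count was 43 with the counting class as a term, 42 of them shared, and 15 within 1 class. Single omissions gave 159 (without ALAN female 3) to 595 (without Midday male 2). Dorsal skin had 4 genes, all lower under ALAN (371 by DESeq2). With single libraries left out the dorsal count ran from 0 to 52, and it was 0 without Midday male 2, a library that stood apart.

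**Figure D4:**
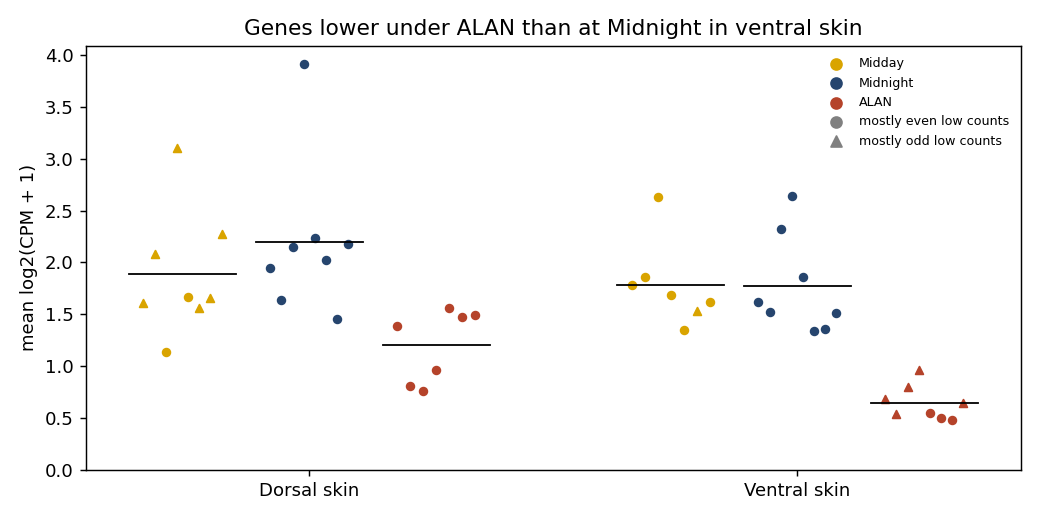
Mean log2(CPM + 1) of the 238 genes lower under ALAN than at Midnight in ventral skin (vertical axis), for each library of dorsal and ventral skin by treatment, with triangles for libraries whose low counts are under 50% even and bars for group means. In ventral skin the 8 ALAN libraries reach at most 0.96, and the 8 Midnight libraries start at 1.34. The genes were chosen by this comparison in these libraries, so a gap between the 2 groups is built in.

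In liver 34 genes were higher and 22 lower under ALAN, and in testes 54 were higher and 20 lower, with median absolute log2 changes of 0.95 and 0.75. In both tissues every ALAN library was of the low-share counting class and no other library was. With an offset per gene for the class, estimated in other tissues, the balance turned, to 30 higher and 44 lower in liver and 74 higher and 167 lower in testes. With single libraries left out the counts ran from 21 to 89 in liver and from 28 to 207 in testes, and with the replicate number as a block they were 28 and 20. In ovary edgeR called 0 genes, with 2664 at an unadjusted p under 0.05 and 380 by DESeq2.

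ALAN against Midday showed what differed between a lit night and day. It gave 1100 genes in eye (384 higher and 716 lower under ALAN), 370 in ventral skin (43 and 327), 146 in liver (48 and 98), 111 in brain (41 and 70), 84 in testes (66 and 18), 11 in ovary (1 and 10) and 10 in dorsal skin (3 and 7). Of the 327 lower in ventral skin, 85 were liver-enriched, 29 eye-enriched and 18 brain-enriched. Ventral skin of Midday female 4 held 5.83% of its counts in liver-enriched genes (next 0.533% among Midday libraries). ENSACAG00000002847 stayed higher than by day under light, by log2 changes of 2.59 ± 0.12 in eye (SE, adjusted p = 5.79e-13, edgeR) and 1.74 ± 0.12 in brain (adjusted p = 1.74e-09). ENSACAG00000002744 stayed lower in brain by a log2 change of -0.85 ± 0.11 (adjusted p = 6.15e-05, edgeR), while in eye its value of -0.39 did not pass the test. With the counting class as a term the count was 86 in eye, 128 in ventral skin, 1 in dorsal skin and 0 in ovary by edgeR (with 583 at an unadjusted p under 0.05, and 568 by DESeq2 without the term), and in liver and testes the class and ALAN cannot be told apart. With single libraries left out it ran from 471 to 2378 in eye, 155 to 376 in ventral skin, 92 to 198 in liver, 67 to 177 in brain, 20 to 81 in testes, 3 to 22 in ovary and 5 to 39 in dorsal skin, without the libraries that stood apart it was 288 in eye, and with the replicate number as a block it was 17 in testes.

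A score per library, the mean log2 CPM of day-high genes minus that of night-high genes, was used to place ALAN animals relative to Midnight and Midday. The genes were chosen from Midday and Midnight replicates 1 and 2, and Midnight replicates 3 and 4 served as the control. In brain, over 66 day-high and 19 night-high genes, the score was -2.41 ± 0.20 under ALAN (SD, n = 8), -2.86 ± 0.16 at Midnight (n = 4) and -1.24 ± 0.07 at Midday (n = 8). ALAN thus lay 0.45 above Midnight, 28.0% of the way to Midday (two-sided exact permutation p = 0.00606, 0.0212 adjusted over 7 tissues). In eye, over 22 day-high and 25 night-high genes, the score was -2.25 ± 0.35 under ALAN (n = 8), -2.98 ± 0.14 at Midnight (n = 4) and -0.52 ± 0.27 at Midday (n = 8), so that ALAN lay 0.73 above Midnight, 29.8% of the way (exact permutation p = 0.00606, 0.0212 adjusted). With Midnight replicates 1 and 2 exchanged for 3 and 4 the shift in brain was 0.27, 21.7% of the way (exact permutation p = 0.0495 adjusted). With the 100 genes of smallest p the shift in eye was 0.37, 20.0% of the way (exact permutation p = 0.0353 adjusted). The Midday libraries that helped to choose the genes also set the end of this scale. Without Midnight male 3 the shift in brain was 0.40 (exact permutation p = 0.0636 adjusted). In each of these tissues 7 of 8 ALAN libraries lay above the highest Midnight library. The shifts of 1.17 in dorsal skin, 0.73 in ventral skin, 0.56 in liver, 0.77 in testes and -0.62 in ovary did not pass the exact permutation test (adjusted p = 0.233 in the first 4 and 0.533 in ovary), and in the gonads the smallest possible p was 0.0667. All 4 control libraries of the eye were of the low-share counting class, against 1 of 8 ALAN libraries. With genes called in at least 2 other tissues the shift was 0.16 in brain (18.1% of the way, adjusted p = 0.125) and 0.41 in eye (19.5%, adjusted p = 0.0533, exact permutation).

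**Figure D5:**
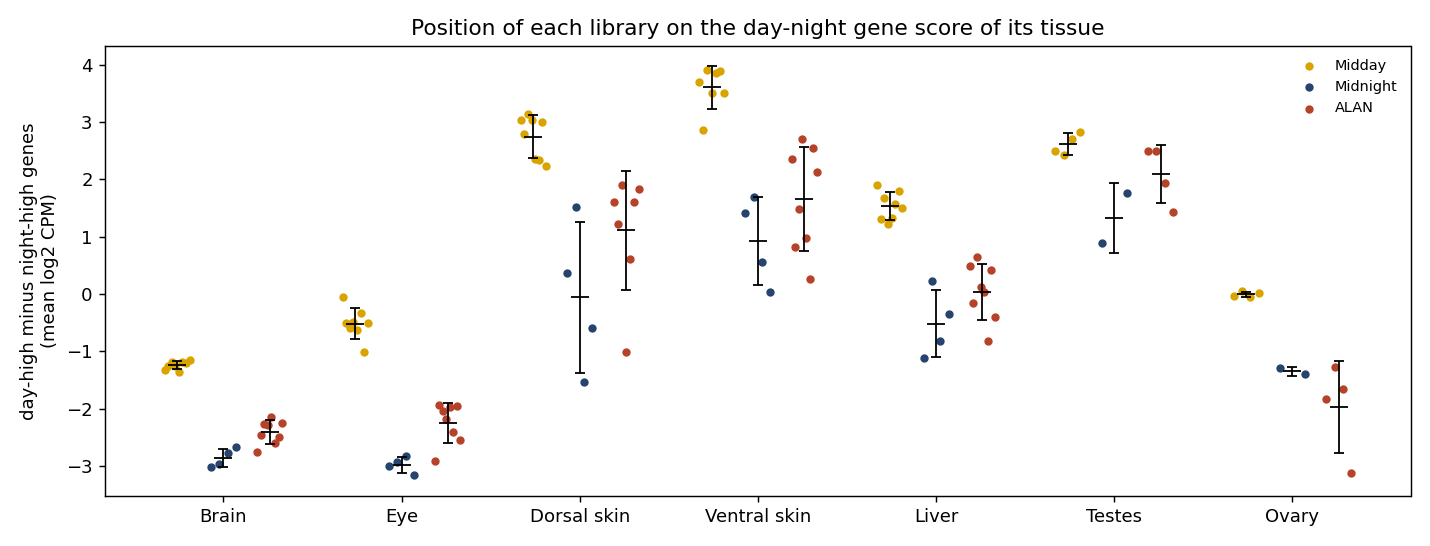
Day-night score of each library (vertical axis, log2 CPM of day-high minus night-high genes) by tissue and treatment, with the mean and SD of each group as bars. In brain and eye the ALAN libraries lie between Midnight and Midday, with 7 of 8 above the highest Midnight library.

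Males and females were compared in their response to light in the 5 tissues with both sexes. EdgeR called 0 genes whose ALAN effect differed between the sexes in brain, eye, dorsal skin, ventral skin and liver. At an unadjusted p under 0.05 there were 1278, 572, 1849, 1087 and 746 genes in that order, and DESeq2 called 11, 1, 14, 120 and 2. In ventral skin the ALAN females and ALAN male 4 were of the low-share counting class and ALAN males 1 to 3 were not. The class and this sex difference were thus largely confounded there. Sex itself separated 426 genes in brain, 449 in eye, 700 in dorsal skin, 36 in ventral skin and 2124 in liver (edgeR). On linkage group b, known as the anole X chromosome, 42 of 62 tested genes differed by sex in brain, 41 of them higher in females (Fisher's exact p = 2.74e-53), and in eye 30 of 62 did, with 28 higher in females (Fisher's exact p = 9.14e-31).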

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

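The test for ovary RNA at a single share of a brain library was chosen only after the result was seen. Of 64 groups of libraries examined, 8 held a library far from the others, and chance gives about 1 in 20.

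The change of ENSACAG00000002847 from Midday to Midnight differed between the 7 tissues (adjusted p = 3.40e-07, edgeR), with the rise seen in 8 of 8 Midnight libraries of the eye and smaller log2 values in the gonads. The change of ENSACAG00000002744 also differed between tissues (adjusted p = 3.86e-04, edgeR), and so did that of ENSACAG00000015032 from Midnight to ALAN (adjusted p = 5.82e-08, edgeR). The latter was chosen for its large change in skin, and 2848 of 20795 genes passed the same test, so its result adds little. The change of ENSACAG00000016775 from Midnight to ALAN did not pass this test (adjusted p = 0.698, edgeR). The fit took no account of the same animals supplying several tissues.

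Single libraries stood far from their group in levels of these genes. In liver, Midday male 4 held ENSACAG00000002847 at 56.8 CPM, where the next Midday library was at 31.2. For ENSACAG00000015032, dorsal skin of Midday female 4 was at 12.0 CPM (next 3.01) and of Midnight female 4 at 32.0 (next 5.05), and these libraries also held the most counts in brain-enriched genes of their groups (0.166%, next 0.0860%, and 0.390%, next 0.0938%). Ventral skin of Midnight female 3 was at 6.40 CPM (next 1.09), with the highest brain-enriched share of its group as well (0.0854%, next 0.0664%), and that of ALAN female 2 at 0.0853 beside 7 libraries at 0, which is a single count. The day-night score of ventral skin in Midday male 2 was 2.86, against 3.51 in the nearest Midday library. The mean level of the 238 genes lower under ALAN was 2.63 in ventral skin of Midday female 4 (next 1.86). That library also held the most counts in liver-enriched genes of its group (5.83%, next 0.533%). So did ventral skin of Midnight female 4 (2.58%, next 0.689%), which had the highest Midnight level of these genes (2.64).

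The brain library of Midnight female 4 held 1.86% of its counts in ovary-enriched genes, against at most 0.159% in the other Midnight brain libraries. Of the 608 genes at least 4-fold higher in it, 41.5% were ovary-enriched, which alone leaves the origin open, and all 20 of the most abundant ovary-enriched genes exceeded every other brain library. Its share of even low counts, 59.9%, lay inside the 59.5% to 62.1% of the other brain libraries, which argues against the way of counting. A mixture of brain with ovary RNA at 19.6% (quartiles 18.2% and 20.9%) gave 95.6% of 589 raised genes within 2-fold of their level, so ovary RNA in this library is a candidate explanation. No biological explanation was tested, and without this library brain gave 257 genes in place of 207 between Midnight and Midday and 177 in place of 111 between ALAN and Midday.

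In ventral skin 238 genes were lower under ALAN, and among the tissues other than skin 116 of them had their highest level in brain, 49 in liver and 44 in eye. The shares over all genes tested there were not computed, so these counts alone point to no tissue. The effect of the counting class, estimated in other tissues, made up 0.00099 of the change (95% interval -0.00272 to 0.00627). The class effects of eye and skin correlated only weakly across genes, so a small part can come from a poor estimate and decides nothing. In ventral skin itself, 3 ALAN libraries of the high-share class had mean levels of the 238 genes of 0.546, 0.499 and 0.478. These lay inside or under the 0.535 to 0.962 of the other ALAN libraries, with Midnight libraries from 1.34 up. The 238 genes were called with these 3 libraries in the ALAN group, so low levels in them are partly built in. With that limit, the levels argue against the class as the whole cause for these genes. With the class as a term all 337 genes kept their direction, and the median absolute log2 change went from 3.09 to 3.28 while its median SE rose from 0.66 to 0.85, so that 42 of the calls remained with the wider error. At the median lowered gene, less RNA of another sampled tissue would explain a part of 0.346 if it came from brain (0.203 to 0.545, at a share of 0.404%), and under 0.03 for eye, liver, ovary or testes (0.0288, 0.00308, 0.00125 and 0.000533), which does not cover the 49 genes highest in liver, 39 of them liver-enriched, taken alone. RNA of brain in the Midnight libraries could thus account for a part of the change and stays open, and an effect of light on the skin remains as well, untested.

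The low-share counting class covered every ALAN library of liver and testes, and a candidate explanation of the class is that fragments were counted in place of reads. In ovary the class effect measured in eye and skin made up 0.0277 (0.00506 to 0.0709) of the change in the 100 genes of smallest p, but edgeR called 0 genes there (2664 at an unadjusted p under 0.05, 380 by DESeq2), so this decides nothing. It made up 0.489 (0.312 to 0.665) of the change called in liver, with the same sign in 50 of 55 genes, and 0.728 (0.467 to 0.907) in testes, with the same sign in 60 of 65. In eye the part was 0.122 (-0.140 to 0.305), which leaves it open, and the class effects of eye and skin correlated at 0.0879 to 0.247 across genes, which are not independent replicates. With this effect taken off, the median absolute log2 change of the called genes went from 0.95 to 0.58 in liver and 0.75 to 0.60 in testes, 74 genes (30 higher, 44 lower) were called in liver, 20 of them shared with the 56, and 241 (74 higher, 167 lower) in testes, 50 of them shared with the 74, so that light and counting cannot be told apart in these tissues.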

How the results depend on the processing

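The counting class as a term, fits within 1 class, fits without the libraries that stood apart, the offset per gene, score genes from other tissues, list counts under other settings, and single omissions for the score and for the ratio of pooled counts were chosen only after the data were examined. The planned gene lists, the clock-gene test and the rule for named genes were not run, since no ID could be paired with a name. With 4 to 8 animals per group, and 4 in the gonads, small changes are missed, and counts of genes near the threshold move with single libraries. Where a value moved and no reason is given, the cause was not tested.

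Under RLE size factors, the counts for the 3 comparisons and the sex difference in the ALAN effect, the list counts, the day-night scores and the printed IDs kept their direction and side of the threshold, with counts within 1.5 times. Sex counts, recurrence and linkage group b were not recomputed under other settings. From Midday to Midnight, the log2 changes of ENSACAG00000002847 in eye and ENSACAG00000002744 in brain kept their direction and side of the threshold under every alternative run. Single omissions gave 3.16 to 3.28 in eye and -1.29 to -1.17 in brain. Their values in other tissues and comparisons, the fall of ENSACAG00000002847 in the lit eye among them, were not examined under the other alternatives. For ENSACAG00000016775 in brain omissions gave 1.02 to 1.24, all past the threshold, while a fit of the 2 groups alone ended the call (1.16, adjusted p = 0.0821). For ENSACAG00000015032 in dorsal skin they gave -7.21 to -5.38, where 16 of 23 omissions ended the call, as did no filter (adjusted p = 0.0643), no sex term (0.0503), the 2 groups alone (0.066), 1 class (0.143) and leaving out the library apart (0.0642). Its Midnight to ALAN ratio fell from 104 to 36.9 in dorsal skin without Midnight female 4, and from 168 to 69.7 in ventral skin without Midnight female 3.

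Values are given in the order ALAN against Midnight, Midnight against Midday and ALAN against Midday. DESeq2 called 70, 370 and 264 genes in brain, 138, 1376 and 2107 in eye, and 371, 278 and 274 in dorsal skin. It called 963, 187 and 757 in ventral skin, 312, 815 and 515 in liver, 545, 21 and 513 in testes, and 380, 66 and 568 in ovary. Its sex differences in the ALAN effect numbered 11 in brain, 1 in eye, 14 in dorsal skin, 120 in ventral skin and 2 in liver.

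With only the 2 groups compared, fewer libraries set the spread. ALAN against Midnight then gave 8 genes in brain, 0 in dorsal skin, 198 in ventral skin and 165 in testes. Midnight against Midday gave 297 in eye and 4 in ovary. ALAN against Midday gave 168 in brain, 416 in eye, 60 in liver, 24 in testes and 1 in ovary. Without a sex term, ALAN against Midnight gave 8 in brain, 0 in dorsal skin and 29 in liver, Midnight against Midday 185 in liver, and ALAN against Midday 5 in dorsal skin. With no filter on low counts, more genes were tested, and ALAN against Midnight gave 2 in dorsal skin, 215 in ventral skin and 19 in liver, and Midnight against Midday 450 in eye. With the replicate number as a block, ALAN against Midnight gave 46 in dorsal skin, 28 in liver and 20 in testes. The block gave 332 in eye and 16 in dorsal skin for Midnight against Midday, and 448 in eye, 17 in testes and 2 in ovary for ALAN against Midday.

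With the counting class as a term, ALAN against Midnight gave 5 in eye, 32 in dorsal skin and 43 in ventral skin, and 12 of 26 day-night sets of other tissues (19 of 36 without the term, which could not be fitted in liver and testes). Midnight against Midday gave 6 in dorsal skin, and ALAN against Midday 86 in eye, 1 in dorsal skin, 128 in ventral skin and 0 in ovary. Within 1 counting class, with fewer libraries, ALAN against Midnight gave 0 in dorsal skin and 15 in ventral skin. Midnight against Midday gave 120 in eye, 3 in dorsal skin and 4 in ovary, and ALAN against Midday 0 in dorsal skin and 21 in ventral skin. The offset per gene gave 241 in testes for ALAN against Midnight. Without the libraries that stood apart, ALAN against Midnight gave 89 in eye, 0 in dorsal skin, 595 in ventral skin and 2 in ovary. Midnight against Midday gave 223 in eye, 54 in dorsal skin, 62 in ventral skin and 2 in ovary, and ALAN against Midday 177 in brain and 288 in eye. With an estimated correlation, 0 day-night sets of other tissues (19 with the preset) and 0 tissue-enriched lists (24) were called between ALAN and Midnight, and 2 tissue-enriched lists (34) between Midnight and Midday.

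The day-night score reversed in ventral skin with Midnight replicates 1 and 2 exchanged for 3 and 4 (-0.0739, adjusted p = 0.901, exact permutation). With genes from other tissues it reversed in ventral skin (-0.104, 0.637), testes (-0.81, 0.0533) and ovary (0.71, 0.0533), and fell short of the threshold in brain (0.16, 0.125) and eye (0.41, 0.0533). Single omissions, with the genes held fixed, gave 0.40 to 0.52 in brain, 0.67 to 0.83 in eye, 0.68 to 1.70 in dorsal skin, 0.43 to 0.98 in ventral skin, 0.36 to 0.80 in liver, 0.34 to 1.20 in testes and -0.86 to -0.24 in ovary. The score fell short in brain without Midnight male 3 (0.40, adjusted p = 0.0636) and passed in dorsal skin without ALAN female 1 (1.52, 0.0444).

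With single libraries left out, counts of genes moved as follows. In brain, ALAN against Midnight ran from 6 to 21: 9 without Midnight male 2, 6 without Midnight male 3, and 8 without ALAN male 3 or ALAN female 3. Midnight against Midday ran from 154 to 257, and ALAN against Midday from 67 to 177: 67 and 73 without Midday males 3 and 4, 68 without ALAN male 1, 72 without ALAN female 3, and 177 without Midnight female 4. The sex difference ran from 0 to 1 (1 without ALAN female 3). In eye, ALAN against Midnight ran from 18 to 64: 53 without Midday female 4, 64 without Midnight male 1 and 55 without ALAN female 3. Midnight against Midday ran from 347 to 1792: 387 without Midday male 1, 1301, 374, 1792 and 412 without Midday females 1 to 4, 347 and 423 without Midnight males 1 and 2, and 429 without Midnight female 2. ALAN against Midday ran from 471 to 2378: 491 without Midday male 1, 2017, 471 and 2378 without Midday females 1 to 3, 518 and 706 without ALAN males 1 and 3, and 718 and 613 without ALAN females 1 and 2. The sex difference ran from 0 to 1 (1 without ALAN female 3).

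In dorsal skin, ALAN against Midnight ran from 0 to 52. It was 0 without any of Midday males 1 to 3, Midday female 2, Midnight males 1 and 2, Midnight female 3, ALAN males 1, 2 and 4 and the 4 ALAN females. It was 49 and 52 without Midday females 3 and 4, 2 without Midnight male 3, 21 without Midnight female 2 and 1 without Midnight female 4. Midnight against Midday ran from 18 to 54: 54 without Midday male 2, 18 without Midday female 2, 20 without Midnight male 3 and 21 without Midnight female 3. ALAN against Midday ran from 5 to 39: 22 without Midday female 3, 39 without Midnight female 4, 6 without ALAN male 1, and 5 without ALAN males 2 or 4 or ALAN female 2. The sex difference ran from 0 to 10 (10 without ALAN female 1). In ventral skin, ALAN against Midnight ran from 159 to 595: 595 without Midday male 2, 165 without Midnight male 1, 174 without Midnight female 4, 160 and 191 without ALAN males 3 and 4, and 159 and 224 without ALAN females 3 and 4. Midnight against Midday ran from 7 to 62: 62 without Midday male 2 and 20 without Midnight female 1. ALAN against Midday ran from 155 to 376: 155 without Midday female 4, and 219 and 208 without ALAN females 1 and 2. The sex difference ran from 0 to 35: 25 without Midday female 1 and 35 without ALAN male 4. Among the ALAN libraries of ventral skin, females 1 to 4 and male 4 were of the low-share counting class. Without male 4, class and sex thus cannot be told apart within ALAN.

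In liver, ALAN against Midnight ran from 21 to 89: 89 and 37 without Midday males 1 and 2, 24, 33 and 22 without Midnight males 1 to 3, 32, 36 and 25 without Midnight females 1 to 3, 25, 21 and 28 without ALAN males 2 to 4, and 33 and 37 without ALAN females 1 and 4. Midnight against Midday ran from 146 to 383: 176 and 174 without Midday females 2 and 3, 199, 146 and 176 without Midnight males 1 to 3, and 193 without Midnight female 3. ALAN against Midday ran from 92 to 198: 92 without Midday female 2 and 94 without ALAN female 2. The sex difference stayed at 0 in edgeR, with 746 genes at an unadjusted p under 0.05 and 2 by DESeq2. In testes, ALAN against Midnight ran from 28 to 207: 207 without Midday male 2, 36, 41 and 40 without Midnight males 1 to 3, 38, 30 and 28 without ALAN males 1, 2 and 4. Midnight against Midday ran from 0 to 1 (1 without Midnight male 4 or ALAN male 1). ALAN against Midday ran from 20 to 81: 26, 26 and 35 without Midday males 1, 2 and 4, 44 and 48 without Midnight males 2 and 3, and 30, 23, 49 and 20 without ALAN males 1 to 4. In ovary, ALAN against Midnight ran from 0 to 1 (1 without ALAN female 3), and Midnight against Midday stayed at 0 in edgeR (593 at an unadjusted p under 0.05, 66 by DESeq2). ALAN against Midday ran from 3 to 22: 3, 6, 7 and 5 without Midday females 1 to 4, 7 without any of Midnight females 1 to 3, and 22 without ALAN females 2 or 3.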

Other observations

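The count over splits of the libraries was planned, and the tests of tissue-enriched lists, day-night sets, recurrence and linkage group b were chosen only after the data were examined. Genes called between Midnight and Midday in brain, eye and liver were taken as sets to the other tissues, and 25 of 36 sets moved in their own direction (camera with a preset correlation), 20 of them also with an estimated one. Between ALAN and Midnight 19 of 36 sets moved, 17 of them toward Midday, but 0 with an estimated correlation (smallest adjusted p = 0.0796). The night-high genes of eye fell in dorsal skin under ALAN (224 of 302 lower, median log2 change -0.18, adjusted p = 8.07e-06 preset and 0.0796 estimated), and the day-high genes of liver rose (139 of 204 higher, median 0.17, 1.52e-05 and 0.0796). By the study's design the same Midnight animals supplied all tissues, and likewise the Midday animals, so the sets and both comparisons share animals. Moves in the set's own direction, or toward Midday under ALAN, can follow from this alone, and how many sets would move for that reason was not computed. Genes called in at least 2 tissues between ALAN and Midnight numbered 11 higher and 6 lower, where shuffled gene labels, which treat the tissues as independent although the same animals supplied them, gave means of 0.628 and 0.616. The low-share counting class held every ALAN library of liver and testes and 5 of 8 of ventral skin, and no Midnight library of these tissues. Shared calls can follow from the counting class too, and how many do was not computed. Between Midnight and Midday 4 genes were higher and 15 lower in at least 3 tissues.

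Genes that differed by sex were more frequent on linkage group b than elsewhere in skin and liver too. In dorsal skin 12 of 62 tested genes there differed by sex (Fisher's exact p = 4.00e-06), in ventral skin 6 of 61 (2.47e-09) and in liver 27 of 60 (3.02e-09). Of 14167 genes tested in all 5 tissues, 9 were higher in females in every one, 3 of them on b, and 0 were higher in males in every one, while 235 were higher in males and 173 in females in at least 2 (edgeR).

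Lists of tissue-enriched genes moved in 24 of 49 tests between ALAN and Midnight with the preset correlation and in 0 with an estimated one. By the preset test liver-enriched genes were lower in 4 tissues and higher in 1, brain-enriched lower in 3 and higher in 1, and eye-enriched lower in 2. Ovary-enriched genes were lower in 6, testes-enriched higher in 4 and lower in 1, and mitochondrial genes higher in 1 and lower in 1. Ovary itself was among the 6 (298 of 374 lower, -0.27, adjusted p = 2.39e-11 preset and 0.599 estimated). There ALAN female 2 held 4.83% of its counts in ovary-enriched genes, against 9.76% to 9.93% in the other ALAN libraries. Whether that fall rests on this library was not examined. Liver-enriched genes were lower in testes under ALAN (287 of 308, median log2 change -2.51, adjusted p = 5.60e-39 preset and 0.51 estimated) and in ventral skin (260 of 311, -1.63, 1.84e-18 and 0.516), but higher in ovary (223 of 296, 1.04, 1.67e-11 and 0.599). Their share of counts varied between testes libraries, from 0.648% to 3.56% at Midnight, 0.235% to 6.08% at Midday and 0.184% to 0.338% under ALAN. In ventral skin Midnight female 4 held 2.58% (next 0.689% among Midnight libraries). Liver RNA in single libraries was thus not told apart from an effect of light. Brain-enriched genes were lower in dorsal skin (141 of 154, -1.49, 8.71e-26 and 0.51) and ventral skin (94 of 116, -0.96, 7.06e-13 and 0.51). Eye-enriched genes were lower in ventral skin (109 of 150, -0.68, 7.75e-11 and 0.230), and ovary-enriched genes in brain (295 of 302, -0.97, 2.21e-12 and 0.599), where the Midnight female 4 library holds the ovary signal. Testes-enriched genes were higher in dorsal skin (693 of 806, 0.87, 7.53e-16 and 0.516). Their share of counts there ran from 0.191% to 1.18% under ALAN, highest in ALAN male 1 (next 0.591%), and from 0.276% to 0.433% at Midnight. Skin-enriched genes moved in no tissue by the preset test (smallest adjusted p = 0.132, in liver). Mitochondrial genes were lower in testes (8 of 9, -0.59, 0.00214 and 0.51) and higher in dorsal skin (13 of 14, 0.38, 0.0206 and 0.599). Between Midnight and Midday 34 of 49 tests passed with the preset correlation, and the skin-enriched (103 of 132 lower, -0.47) and liver-enriched genes (157 of 229 lower, -0.21) of brain also passed with an estimated one (adjusted p = 0.00306 and 0.0202). Between ALAN and Midday 32 of 49 passed with the preset and 4 with an estimated correlation. In ventral skin liver-enriched genes were lower there (280 of 311, -2.27, camera adjusted p = 2.06e-26 preset and 0.355 estimated), as were eye-enriched genes (123 of 150, -1.29, 5.43e-24 and 0.00227).

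Residuals of libraries of the same treatment, sex and number were alike across tissues, and a candidate explanation is that a number marks the same animal. In 95.5% of 22 pairs of dorsal and ventral skin the best match was the library of the same number (permutation p = 0.0001, the smallest these permutations can give), and all 24 brain libraries matched best with their own number in eye and in liver. The match was weaker for other pairs, such as dorsal skin with testes (36.4%, permutation p = 0.0114) and with ovary (41.7%, 0.0491), and 58.3% for testes with liver, ventral skin or eye. The ovary library of ALAN female 2 had 1781 genes raised at least 4-fold, and 4.49% of them were enriched in testes, the best other tissue, which argues against RNA of another sampled tissue as the whole cause. Its median correlation with other ovary libraries was 0.919, while the other low-share libraries started at 0.967, inside the 0.966 to 0.975 of the high-share class, which argues against the way of counting, and what set it apart stays open.

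Other splits of the libraries into groups of the same sizes were fitted, 30 drawn from the many possible in tissues of both sexes and all 35 in gonads, the real split included. For ALAN against Midnight, 1 split, the real one itself, gave as many genes in brain (15, highest other 0), eye (26 and 0), dorsal skin (4 and 1), ventral skin (337 and 1), liver (56 and 1) and testes (74 and 1), while in ovary all 35 splits did so (0 by edgeR and 1). A share of 1 in 30 or 1 in 35 is the smallest these splits can give. It was not adjusted over the tissues and comparisons, so it does not exclude chance. In dorsal skin the count of 4 also moved in 19 of 23 single omissions. For Midnight against Midday, 1 split did so in brain (207 and 1), eye (720 and 44), dorsal skin (35 and 0) and liver (309 and 19), 35 in testes (0 and 2) and 35 in ovary (0 and 0), and 3 of 30 in ventral skin (10), where another split gave 2039 genes, which points to a structure of the samples, whose nature was not tested. For ALAN against Midday, 1 split did so in brain (111 and 0), eye (1100 and 1), ventral skin (370 and 1), liver (146 and 17), testes (84 and 0) and ovary (11 and 1), and 2 of 30 in dorsal skin (10), where another gave 155 genes, which again points to a structure of the samples, not tested further. For sex, 1 split did so in brain (426 and 10), eye (449 and 2), dorsal skin (700 and 0), ventral skin (36 and 5) and liver (2124 and 1). For the sex difference in the ALAN effect all 30 did so in each of the 5 tissues, with 0 by edgeR and at most 1 in brain, eye and liver, 5 in dorsal skin and 54 in ventral skin. Where the real count is 0 every split reaches it, so these splits decide nothing, and chance cannot be excluded for Midnight against Midday in ventral skin and ALAN against Midday in dorsal skin.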
